A study of Drosophila melanogaster with 18 samples.

How the data were processed

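RNA was measured in whole heads of Drosophila melanogaster kept at 25 °C. The samples were 3 libraries each of wild-type and foxo mutant females at day 3 and of wild-type males at days 3, 15, 30 and 45, named here by group and replicate number. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected and libraries were made with the NEBNext Ultra kit, which is not said to mark strand. Per the submitters' processing notes, reads were aligned with STAR to dm6, counted with HTSeq and compared with DESeq, with no versions given.

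The male table was deposited as 1 normalized value per gene and library, a signal that the authors scaled with DESeq, per the submitters' processing notes. Every value lay within 0.001 reads of a whole multiple of its library's value of one read, 0.836 to 1.22, so whole read counts were recovered from the deposited values for 10884 genes and libraries of at least 2999956 reads. At these depths one read is about 1 normalized count, and genes near the filter below rest on few reads. The female table was deposited as the authors' comparison alone, with no value per library. It gives 10480 genes with a mean of normalized counts, a log2 fold change that the authors computed of mutant over wild type with its standard error, a test statistic (a score the authors deposited), and the authors' deposited p-value and adjusted p-value. Of these genes 11 have no p-value and 620 no adjusted p-value. The fold direction was read from the table's name and checked against wild-type male levels. Whether the authors' fold changes were shrunken is not given in the sources used here. Their standard errors were small even at very low means, as for CecA2 (0.052 at a mean of 2.08) and CecA1 (0.118 at 8.19). Shrunken estimates have this property, so the folds were probably shrunken and may be smaller than age folds computed without shrinkage.

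Genes of the male table were matched by FlyBase identifier to Ensembl annotation of dm6, which named 10701 and left 183 without a symbol. Names in the female table were matched by symbol (8340) or synonym (2020), and 120 were not matched. For ages, log2 of the normalized value plus 1 was fitted by limma with an intensity trend, in 1 model of the 4 ages, for 8921 genes with at least 10 in at least 3 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Each later age was compared with day 3, and each age after day 15 with the age before, and any difference between ages was tested with the moderated F test. The mutant was to be tested from values per library in the same way. With the authors' comparison alone, their adjusted p was used at the same threshold, and gene lists were described by counts and by the percentile of the median among 10000 random lists matched on mean level.

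The 32 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. With age they were tested by limma's camera with the preset correlation of 0.01 between genes and again with an estimated correlation, for lists of at least 5 tested members, and adjusted over lists. Counts over list members were also made with p-values adjusted over the list alone. Genes called lower or higher in the mutant were taken as 2 further lists into the age test, and overlaps of calls were tested with Fisher's exact test, two-sided. The genes named for each main comparison (mutant against wild type, and day 45 against day 3) were foxo, the 8 higher and the 8 lower named genes of largest change among calls with a mean of at least 50 and libraries that did not overlap, where values per library exist, the 3 of largest change under any name each way, and every FOXO target. To these were added up to 4 members of each list, those of largest change among its calls or of highest mean where none passed, and the 8 genes of largest joint change in each direction among calls of both comparisons. Where named genes were recognised as having near-identical copies, or as overlapping or antisense genes, this is said beside them.

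The age test was run on simulated counts with 200 changed genes among 10884, using the means and library sizes of the males. It recovered 53.7% of genes changed 1.5-fold, 80.6% at 2-fold and 95.5% at 4-fold, with 10 false calls (6.1%), and 2.5% of 200 unchanged lists had a camera p under 0.05. Genes were simulated as independent and these lists were random. The simulation therefore does not check camera for lists of correlated genes, such as ribosomal protein genes (estimated correlation 0.827). Alternatives for ages left out each library, put the replicate number in the model, rescaled by TMM, changed the filter, the pseudocount, the smallest fold and the libraries of the fit, or tested the recovered reads with DESeq2 or edgeR. The closing section gives their effect. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not used here, and GC content was not examined because no genome sequence was used.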

Results

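Polyadenylated RNA was measured in the heads of the fruit fly Drosophila melanogaster, to find the genes that depend on foxo and to follow those genes through adult life. The gene foxo encodes the fly's FOXO transcription factor, which insulin signalling keeps out of the nucleus. The study held 18 libraries in 6 groups of 3. Of these, 6 came from females 3 days after eclosion, 3 of them from the w1118 control line (called wild type below) and 3 from mutants homozygous for the foxo allele c431. The other 12 came from wild-type males at 3, 15, 30 and 45 days. The male libraries held at least 2999956 recovered reads each over 10884 genes. For the females, values were read from the authors' deposited table, which compares mutant with wild type for 10480 genes, and the depth of each female library was not given in the sources used here. The labels do not say whether replicates were separate cultures or collections of flies, so p-values measure the spread between these samples.

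The targeted gene was examined first. The gene foxo (FBgn0038197) lies on chromosome arm 3R at 14056945 to 14087978 in dm6 coordinates. Its mRNA was 1.25-fold higher in the mutant females than in wild type (log2 change 0.33, SE 0.09, adjusted p = 0.00465 in the authors' deposited table). The lesion of the mutant allele was not given in the sources used here, so the mRNA level does not check the genotype label. In wild-type males foxo mRNA stood at 391 ± 23.4 normalized counts at day 3 and 397 ± 23.6 at day 15, then at 477 ± 13.7 at day 30 and 474 ± 24.9 at day 45 (SD, n = 3 each). It rose 1.21-fold from day 3 to day 45 (log2 change 0.28, SE 0.08, limma adjusted p = 0.00916), and the lowest day 45 library, at 445.5, lay above the highest day 3 library, at 411.

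**Figure D1:**
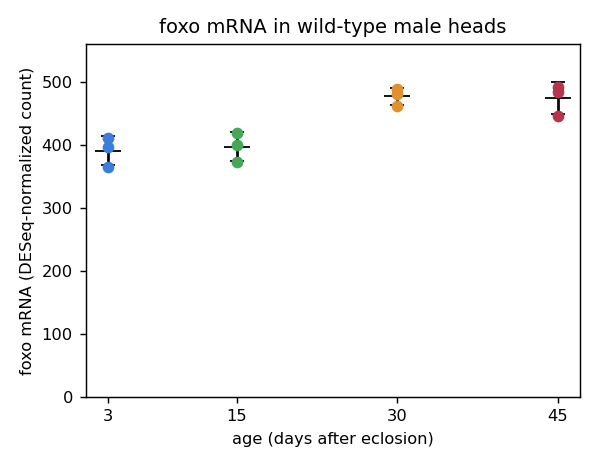
Normalized foxo counts (y axis, starting at 0) in the heads of wild-type males at 3, 15, 30 and 45 days after eclosion (x axis). Each point is 1 library, the long dash the mean of 3 libraries and the bar 1 SD, and the means were 391, 397, 477 and 474.

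The comparison of foxo mutant with wild-type females at day 3 asked which genes depend on foxo in the young head. Of synapse and ion channel genes 25 of 45 were lower in the mutant and of phototransduction genes 13 of 30, while 47 of 82 ribosomal protein genes, 9 of 27 humoral immunity genes and 9 of 14 blood cell genes were higher, with the yolk protein genes. In the authors' deposited table, 617 genes were higher and 642 lower in the mutant at an adjusted p under 0.05, 12.8% of the 9860 genes with an adjusted p. Most changes were small, with 57 genes at least 2-fold higher and 39 at least 2-fold lower in the authors' deposited table. Its fold changes were probably shrunken, which may have lowered these counts. The signs of the changes were checked against the wild-type males: at day 3 these lay nearer to the wild-type than to the mutant level for 80.8% of 496 genes with an absolute log2 change over 0.5.

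Among genes with a given name and a mean of at least 50, the steepest loss in the authors' deposited table was that of sordd2 (X, 15796908 to 15799162), at a log2 change of -4.13 (17.5-fold lower, SE 0.21, adjusted p = 7.47e-86). Under the same limits it was followed in the authors' deposited table by the transporter MFS3 (-1.98), the polyubiquitin gene Ubi-p5E (-1.74), aay (-1.50), which encodes phosphoserine phosphatase, and the cytochrome P450 Cyp6a17 (-1.50). The next losses under these limits in the authors' deposited table were those of Hpd, an enzyme of tyrosine breakdown (-1.42), the imaginal disc growth factor Idgf5 (-1.34) and lactate dehydrogenase, Ldh (-1.24). Between sordd2 and MFS3 lay genes without a given name: CG3397 (3R, 11983098 to 11984541) stood at -3.40 and the antisense RNA asRNA:CR45600 (3R, 15136985 to 15140121) at -3.06 in the authors' deposited table. The library kit is not said to mark strand, so reads of asRNA:CR45600 and of the genes it overlaps cannot be told apart, and CG3397 and Ubi-p5E have close paralogs with which reads may be shared.

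Among genes with a mean of at least 50, the largest gains in the authors' deposited table were those of CG4962 (log2 change 2.30, SE 0.17, adjusted p = 1.18e-36), the peroxiredoxin Prx6c (1.92), CG7054 (1.89) and the drosomycin-like peptide Drsl4 (1.86). Of genes with a given name and such a mean, the receptor mthl8 (1.63), the tubulin betaTub60D (1.44), Kaz1-ORFB (1.43), Mec2 (1.42), the fat body and feeding gene fit (1.34) and LKR (1.24) came next in the authors' deposited table. Prx6c has a near copy, Prx6b, that was also higher in the authors' deposited table (log2 change 1.07), and the split of reads between them is uncertain.

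Genes of synapse and neuronal excitability were called in 1 direction. Of their 45 members 25 were lower and 0 higher in the authors' deposited table (32 and 0 adjusted over the list alone). The list's median log2 change of -0.25 in the authors' deposited table lay below those of all 10000 random lists matched on mean level. Random lists were not matched on exon length, which correlated across genes with the mutant change (Spearman -0.258), and this holds for every percentile below. Examples from the authors' deposited table were the microtubule protein gene futsch (log2 change -0.52, SE 0.09, adjusted p = 2.06e-07), the GABA receptor Rdl (-0.46), the monoamine transporter Vmat (-0.45) and the ankyrin Ank2 (-0.43). Of 30 phototransduction genes, 13 were lower and 2 higher (16 and 2 adjusted over the list alone), with the median at percentile 0.02 of random lists in the authors' deposited table. The calcium-binding photoreceptor protein gene Cpn (-0.83), the protein kinase inaC (-0.57) and rdgB (-0.51) were lower and the carotenoid oxygenase ninaB was higher (0.61) in the authors' deposited table. Glial genes gave 2 higher and 2 lower of 15 (2 and 2 adjusted over the list alone), with a median of -0.003 at percentile 63.2 in the authors' deposited table.

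Hemocyte and head fat body genes were on the higher side. For hemocytes, the circulating blood cells, 9 of 14 genes were higher and 0 lower in the authors' deposited table (9 and 0 adjusted over the list alone), with a median log2 change of 0.34 above all random lists. They included the prophenoloxidases PPO1 (0.61) and PPO2 (0.59), the collagen Col4a1 (0.58) and the phagocytic receptor eater (0.45) in the authors' deposited table. Of 15 head fat body genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone) in the authors' deposited table, with the median of 0.27 at percentile 99.99. Of 7 sex label genes 4 were higher and 0 lower (4 and 0 adjusted over the list alone) in the authors' deposited table. The gene fit, the yolk protein genes Yp2 (1.21), Yp3 (0.95) and Yp1 (0.81) and the gene takeout, to (1.02), were higher in the authors' deposited table. Of these, fit and the yolk protein genes belong to both the head fat body and the sex label list, so the results of those lists are not separate. Of 27 humoral immunity genes 9 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.31 above all random lists in the authors' deposited table. The recognition protein PGRP-SA (log2 change 1.07) and the antimicrobial peptides Drs (0.82), CecC (0.77) and Def (0.71) were the largest of these in the authors' deposited table. Muscle genes gave 6 higher and 1 lower of 26 (10 and 1 adjusted over the list alone), with the median at percentile 92.5 in the authors' deposited table, Act88F (0.72) and Act87E (0.51) among the higher ones.

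Cytosolic ribosomal protein genes were higher as a group, with 47 of 82 higher and 0 lower in the authors' deposited table (71 and 0 adjusted over the list alone) and a median log2 change of 0.20 above all random lists. Each change was small in the authors' deposited table, as for RpS15Aa (0.33, SE 0.06), RpL21 (0.32) and RpL7A (0.32). Of 59 respiratory chain genes only 3 were higher and 1 lower (2 and 0 adjusted over the list alone), though the median of 0.05 lay at percentile 99.7 in the authors' deposited table.

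Detoxification genes came next. Of 29 glutathione S-transferase genes 0 were higher and 6 lower in the authors' deposited table (0 and 7 adjusted over the list alone), with the median at percentile 0.025. The lower ones in the authors' deposited table included GstE1 (log2 change -0.83), GstS1 (-0.75), GstE11 (-0.68) and GstE9 (-0.55). Of 37 xenobiotic cytochrome P450 genes 4 were higher and 10 lower (6 and 12 adjusted over the list alone), with the median at percentile 2.81 in the authors' deposited table, inside the central 95% of random lists. Cyp6a17, Cyp4e3 (-1.24) and Cyp6g1 (-0.92) were lower and Cyp4s3 higher (1.36) in the authors' deposited table. Of 14 antioxidant enzyme genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone) in the authors' deposited table, Prx6c and Prx6b being higher and catalase, Cat, lower (-0.38), with the median at percentile 98.0. Of 15 heat shock and chaperone genes 0 were higher and 2 lower (0 and 2 adjusted over the list alone), namely Hsp26 (-0.62) and the co-chaperone stv (-0.40), with the median at percentile 0.69 in the authors' deposited table.

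Genes taken from the literature as FOXO targets were, on balance, lower. Of 11 such genes 4 were lower and 1 higher in the authors' deposited table (5 and 1 adjusted over the list alone), with a median log2 change of -0.20 at percentile 1.48. The stress sensor Sesn (-0.85, SE 0.09, adjusted p = 3.76e-19), the insulin-like peptide Ilp6 (-0.76, adjusted p = 2.87e-07), the small heat shock protein gene l(2)efl (-0.49) and the autophagy gene Atg8a (-0.24) were lower, and srl, the fly PGC-1 coactivator, was higher (0.56) in the authors' deposited table. The translation repressor Thor (-0.23, adjusted p = 0.0656) and the insulin receptor InR (-0.20, adjusted p = 0.428) did not pass in the authors' deposited table, nor did the lipases bmm (-0.08) and Lip4 (0.20), the lipocalin NLaz (0.25) or FoxK (0.03). Of 21 insulin and TOR pathway genes 2 were higher and 4 lower (2 and 6 adjusted over the list alone), with the median at percentile 1.82 in the authors' deposited table. Among them in the authors' deposited table the insulin antagonist ImpL2 was higher (1.09) and the insulin-like peptide Ilp3 lower (-1.04).

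Lists of metabolism, the senses and cell maintenance follow with their counts. Lipid storage and turnover gave 4 higher and 8 lower of 27 (4 and 8 adjusted over the list alone, percentile 27.9) in the authors' deposited table. There yip2 was lower (-0.84) and ATPCL higher (0.56) in the authors' deposited table. Glycolysis gave 1 higher and 3 lower of 12 (1 and 5 adjusted over the list alone, percentile 23.9) in the authors' deposited table. The TCA cycle gave 1 higher and 2 lower of 18 (1 and 2 adjusted over the list alone, percentile 33.7) in the authors' deposited table. Odorant binding proteins and olfactory reception gave 3 higher and 5 lower of 35 (3 and 7 adjusted over the list alone, percentile 28.1) in the authors' deposited table. The circadian clock gave 2 and 2 of 12 (2 and 2 adjusted over the list alone, percentile 69.9) and autophagy 1 and 3 of 23 (1 and 3 adjusted over the list alone, percentile 90.8) in the authors' deposited table. Cuticle genes gave 4 higher and 0 lower of 25 (4 and 0 adjusted over the list alone, percentile 85.3) in the authors' deposited table. The proteasome gave 0 and 1 of 33 (0 and 1 adjusted over the list alone, percentile 84.1) and JNK and apoptosis response 1 and 1 of 21 (1 and 1 adjusted over the list alone, percentile 83.3) in the authors' deposited table. DNA damage and cell cycle gave 2 higher and 0 lower of 30 (1 and 0 adjusted over the list alone, percentile 70.0) in the authors' deposited table. Ovary and eggshell gave 0 and 1 of 13 (0 and 0 adjusted over the list alone, percentile 98.4) and digestive enzymes of the gut 0 and 0 of 16 (0 and 0 adjusted over the list alone, percentile 99.5) in the authors' deposited table. Polycomb and Trithorax genes gave 0 and 0 of 22 (0 and 0 adjusted over the list alone, percentile 7.54) in the authors' deposited table. Turandot stress peptides (4 genes) and the male reproductive tract (3 genes) gave 0 either way, over all genes and adjusted over the list alone, in the authors' deposited table.

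Around foxo itself, 17.4% of the 144 genes within 1 Mb were called in the authors' deposited table against 12.7% elsewhere (Fisher's exact test, two-sided, p = 0.102, adjusted p = 0.17). In wider windows, chosen after the data were seen, the same test on the authors' deposited table passed, with 19% called within 2 Mb against 12.5% elsewhere (p = 0.000812, adjusted p = 0.00406) and 16% within 5 Mb against 12.4% (p = 0.00316, adjusted p = 0.0105). Chromosome arm 3R, which carries foxo, held 14.3% called genes against 12.3% elsewhere by the same test on the authors' deposited table (p = 0.0105, adjusted p = 0.0262). The small arm 4 held 26.2% of 84 genes (adjusted p = 0.00406), by the same test on the authors' deposited table. The percentiles against random lists treat genes as independent and come from single values per gene in the authors' deposited table, so no estimated correlation between genes could be used.

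The ages of wild-type males were compared to follow transcript levels through adult life. In heads of 45-day-old males, humoral immunity genes stood above day 3 by a median log2 change of 2.88, or 1.40 among genes with a mean of at least 50 and 1.79 with a pseudocount of 10. Genes of ribosomes, proteasomes and lipid turnover were also higher, and genes of the respiratory chain, synapses, phototransduction and muscle lower. None of these list calls held with an estimated correlation between genes (limma camera adjusted p = 0.159 for humoral immunity and at most 0.383 for the others). From day 3 to day 45, 1555 genes rose and 1629 fell among 8921 tested (35.7%, limma adjusted p under 0.05), of which 252 rose and 173 fell at least 2-fold. The first principal component, 44.9% of the variance, ordered the ages from day 3 to day 45.

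**Figure D2:**
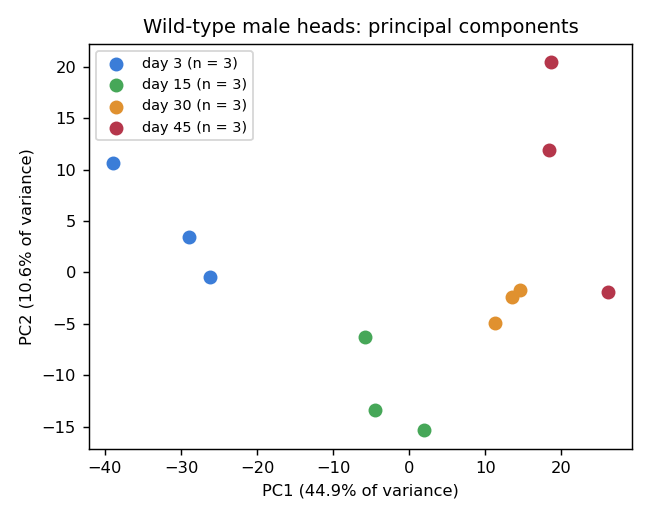
Scores of the 12 wild-type male head libraries on the first and the second principal component of log2 normalized counts (x axis, 44.9% of variance; y axis, 10.6%). Each point is 1 library, coloured by age with 3 per age, and the first component runs from -38.9 for a day 3 library to 26.1 for a day 45 library.

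Humoral immunity genes changed most with age. Of 29 tested, 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 change of 2.88 (limma camera adjusted p = 1.07e-19, adjusted p = 0.159 with an estimated correlation). The antibacterial diptericin gene DptA (2R, 18865765 to 18866260) went from 17.1 ± 9.06 normalized counts at day 3 to 749 ± 423 at day 45 (SD, n = 3 each; log2 change 5.35, SE 0.50, limma adjusted p = 5.29e-07). Attacin AttC went from 75.9 ± 36.8 to 2579.5 ± 1509.9 (log2 change 5.03), and the peptidoglycan amidase PGRP-SC2 from 2.44 ± 2.22 to 103 ± 36.7 (5.04; 3.15 with a pseudocount of 10). CecA1 (5.42), AttB (4.65), DptB (4.55), CecA2 (4.54) and Dro (4.34) rose with them, and reads of CecA1 and CecA2, DptA and DptB and the attacins may be shared between close copies. The list's median stood at 0.44 at day 15 and 1.56 at day 30. The Turandot stress peptides went down instead: 3 of 4 fell (3 adjusted over the list alone; too few members for a list test). The calls of TotM and TotC were lost with DESeq2 on recovered reads (adjusted p = 0.0592 and 0.0773), and that of TotC without day 45 replicate 2 (limma adjusted p = 0.0584). TotA went from 5317 ± 176 to 3175.5 ± 1019 (log2 change -0.80, limma adjusted p = 0.00234), while TotX did not pass (0.05).

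Neuronal genes fell. Of 44 synapse and neuronal excitability genes 38 fell and 0 rose (39 and 0 adjusted over the list alone), with a median log2 change of -0.55 (limma camera adjusted p = 1.64e-18, adjusted p = 0.236 with an estimated correlation). The GABA-synthesizing enzyme gene Gad1 went from 2441.5 ± 336 to 1012 ± 106 (SD, n = 3 each; log2 change -1.27, SE 0.11, limma adjusted p = 2.2e-07), and the vesicle release gene cpx from 12679 ± 1449 to 6334.5 ± 438. The calcium sensor gene Syt1 (-0.95) and the acetylcholine receptor subunit gene nAChRbeta1 (-0.95) fell with them. Phototransduction gave 20 lower and 3 higher of 30 (21 and 3 adjusted over the list alone), with a median of -0.58 (limma camera adjusted p = 8.43e-08, adjusted p = 0.239 with an estimated correlation). Within this list, the corneal protein gene retinin fell by 2.12 on the log2 scale. The carotenoid receptor gene ninaD fell by 1.47, and Gbeta76C and inaD by 1.12 and 1.08. Glial genes moved both ways, 8 falling and 5 rising of 15 (9 and 5 adjusted over the list alone; limma camera adjusted p = 0.177), with the GABA transporter Gat at -1.03 and wrapper at 0.87. Beside these lists, markers of head fat body gave 5 higher and 1 lower of 13 (5 and 1 adjusted over the list alone; median 0.17, limma camera adjusted p = 0.206). Hemocytes gave 4 higher and 5 lower of 12 (4 and 5 adjusted over the list alone; median 0.08, limma camera adjusted p = 0.799).

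Muscle genes were lower by day 15, when 22 of 23 were called and the list median was -0.89. It stood at -0.81 at day 45, with 20 of 23 lower and 0 higher (20 and 0 adjusted over the list alone; limma camera adjusted p = 6.8e-12, adjusted p = 0.239 with an estimated correlation). Myosin light chain Mlc2 went from 2263 ± 907 at day 3 to 813 ± 8.19 at day 45 (SD, n = 3 each; log2 change -1.40, limma adjusted p = 6.37e-06). Act88F fell by 1.65, Zasp66 by 1.31 and Mlc1 by 1.26 on the log2 scale. Respiratory chain genes fell almost without exception: 59 of 61 fell and 0 rose (59 and 0 adjusted over the list alone), with a median of -0.57 (limma camera adjusted p = 8.76e-24, adjusted p = 0.236 with an estimated correlation). Their examples are UQCR-Q (-0.85), UQCR-6.4 (-0.80), ND-19 (-0.78) and ATPsynF (-0.78). Of 17 TCA cycle genes 11 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.35 (limma camera adjusted p = 0.00185, adjusted p = 0.284 with an estimated correlation). They were led by the citrate synthase kdn (-1.02) and the isocitrate dehydrogenase subunit Idh3a (-0.88).

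Transcripts of the mitochondrial genome gave 5 lower and 1 higher of 15 (5 and 1 adjusted over the list alone; median -0.25, limma camera adjusted p = 0.0161, adjusted p = 0.582 with an estimated correlation). This list lost its call without day 45 replicate 1 (median -0.11, limma camera adjusted p = 0.14). The mitochondrial ribosomal RNA mt:lrRNA went from 240510.0 ± 20532 normalized counts at day 3 to 96016 ± 8914 at day 45 (SD, n = 3 each; log2 change -1.33, limma adjusted p = 2.61e-06), and mt:srRNA fell by 1.57 on the log2 scale. The 10 genes with the most reads in a library held 15.3% to 15.8% of its reads at day 3 and 10.2% to 12.8% at day 45. Glycolysis gave 2 higher and 4 lower of 13 (2 and 4 adjusted over the list alone; limma camera adjusted p = 0.301), with Ldh at 1.64 and Gapdh1 at -0.60.

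Ribosomal protein and proteasome genes rose. Of 77 cytosolic ribosomal protein genes 59 rose and 0 fell (68 and 0 adjusted over the list alone), with a median log2 change of 0.36 (limma camera adjusted p = 6.85e-18, adjusted p = 0.383 with an estimated correlation). RpS27 (0.66) and sta (0.59) are examples. Of 33 proteasome list genes 26 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.32 (limma camera adjusted p = 6.99e-09, adjusted p = 0.236 with an estimated correlation). They included the core subunit gene Prosalpha3, from 197 ± 17.8 to 298 ± 17.3 (SD, n = 3 each; log2 change 0.60, limma adjusted p = 6.24e-05), and cnc (0.58), the fly homolog of the Nrf transcription factors that activate proteasome genes. Autophagy gave 2 higher and 0 lower of 23 (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.799), the receptor ref(2)P (0.51) and Atg13 (0.43).

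**Figure D3:**
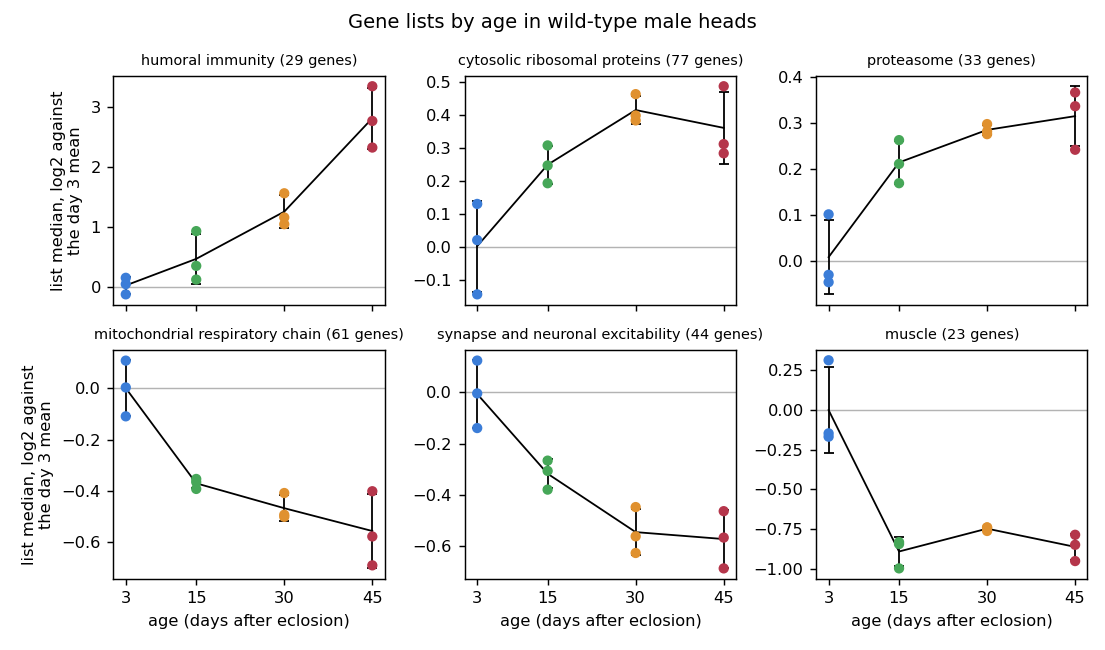
Median log2 change of 6 gene lists against the day 3 mean (y axis, each panel with its own scale) in wild-type male heads by age in days (x axis), with 1 point per library, a line through the means of 3 libraries and bars of 1 SD. Humoral immunity reaches 2.81 at day 45 in the mean of its libraries, ribosomal proteins 0.36 and the proteasome 0.32, while the respiratory chain reaches -0.56, synapse and neuronal excitability -0.57 and muscle -0.86.

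Lipid storage and turnover genes rose as well, 15 of 24 with 0 falling (17 and 0 adjusted over the list alone), at a median of 0.33 (limma camera adjusted p = 5.06e-06, adjusted p = 0.239 with an estimated correlation). The perilipin gene Lsd-1 (0.76), the lipoprotein assembly gene Mtp (0.73) and the triglyceride lipase bmm (0.61, SE 0.12) led this list. Of 29 glutathione S-transferase genes 11 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.42 (limma camera adjusted p = 0.00343, adjusted p = 0.383 with an estimated correlation). GstD2 rose by 1.93 on the log2 scale and GstE14 fell by 0.83. Xenobiotic cytochrome P450 genes gave 10 higher and 3 lower of 35 (10 and 3 adjusted over the list alone; median 0.21, limma camera adjusted p = 0.0161, adjusted p = 0.451 with an estimated correlation). Cyp4d1 (2.15) and Cyp4d21 (1.01) rose and Cyp4s3 (-0.94) fell. At day 3 and at day 45, the library farthest from the mean of its age on the first and second principal components was picked after the data were seen. This rule names a library at each age even where none is an outlier. The libraries so picked, day 3 replicate 1 and day 45 replicate 3, are called those that stood apart and were left out. Without them the P450 list lost its call (median 0.11, limma camera adjusted p = 0.104; median 0.13 without day 45 replicate 3 alone), and the medians of glutathione S-transferases and ribosomal proteins were 0.18 and 0.22. Antioxidant enzymes gave 4 higher and 1 lower of 14 (4 and 1 adjusted over the list alone; limma camera adjusted p = 0.272), with Trxr1 at 0.52 and Sod2 at -0.45.

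Stress response genes differed by list. JNK and apoptosis response genes rose, 9 of 17 with 1 falling (9 and 1 adjusted over the list alone), at a median of 0.31 (limma camera adjusted p = 0.0042, adjusted p = 0.236 with an estimated correlation). Gadd45 (1.79), the ETS factor Ets21C (1.37), the matrix metalloproteinase Mmp1 (1.05) and the stress-response factor Xrp1 (0.95) rose and the JNK gene bsk itself fell by 0.53. DNA damage and cell cycle genes gave 7 higher and 1 lower of 24 (7 and 0 adjusted over the list alone; median 0.27, limma camera adjusted p = 0.0253, adjusted p = 0.236 with an estimated correlation). They were led by the Ku subunit genes Irbp (2.64-fold) and Ku80 (2.46-fold). The list's call was lost without day 45 replicate 1 (limma camera adjusted p = 0.0541) and without both libraries that stood apart (adjusted p = 0.0547). Heat shock and chaperone genes gave 3 higher and 6 lower of 15 (3 and 7 adjusted over the list alone; median -0.04, mean -0.68, limma camera adjusted p = 0.413). The lower ones included Hsp26, from 163 ± 43.2 to 31.5 ± 9.71 (SD, n = 3 each; log2 change -2.34, limma adjusted p = 6.4e-05), Hsp27 (-1.72) and Hsp70Bb (-2.95), whose reads may be shared with its near-identical copies.

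Cuticle genes gave 6 lower and 2 higher of 11 (6 and 2 adjusted over the list alone; median -0.56, limma camera adjusted p = 0.0197, adjusted p = 0.236 with an estimated correlation). Cpr49Ag fell from 280.2 ± 51.1 to 39.4 ± 14.8 and Cpr49Ae from 333 ± 60.9 to 56.5 ± 8.69 (SD, n = 3 each; log2 changes -2.85 and -2.54, limma adjusted p = 2.93e-08 and 5.86e-09). Other steep losses were those of the calcium-binding protein gene Scp1 (-3.03), Loxl2 (-2.27), the neuropeptide precursor Nplp3 (-2.15) and Cpr11B (-2.12). Genes without a given name fell further, CG7203 from 1495 ± 2088 to 36.7 (log2 change -4.25) and CG4000 from 961 ± 873 to 69.2 (-3.42; SD, n = 3). Without day 3 replicate 1 the gene CG7203 at day 45 stood at -3.002 and the gene CG4000 at day 45 at -2.715. The gene CG7214 at day 45 stood at -4.53, and at -2.48 without day 3 replicate 1, the library in which it was high.

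The roX RNAs of the male X chromosome dosage compensation complex fell, lncRNA:roX1 from 7104.5 ± 142 to 4019.9 ± 219 (SD, n = 3 each; log2 change -0.82, SE 0.07, limma adjusted p = 2.23e-07). Likewise lncRNA:roX2 fell by 0.98 on the log2 scale. As a list the sex labels gave 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone; limma camera adjusted p = 0.302), and the yolk protein gene Yp1 had at most 10.95 normalized counts in any male library. Odorant binding proteins and olfactory reception gave 6 higher and 3 lower of 30 (6 and 3 adjusted over the list alone; limma camera adjusted p = 0.503), with Obp56a at 2.90. The circadian clock gave 1 and 2 of 12 (1 and 2 adjusted over the list alone; limma camera adjusted p = 0.799), with the neuropeptide Pdf at 0.87 and its receptor Pdfr at -0.56. Polycomb and Trithorax genes gave 0 and 1 of 23 (0 and 1 adjusted over the list alone; limma camera adjusted p = 0.613). Digestive enzymes of the gut gave 3 and 0 of 9 (4 and 0 adjusted over the list alone; limma camera adjusted p = 0.272), with the amylase Amy-p at 1.85 and its near copy Amy-d at 1.04, between which reads may be shared. The ovary and eggshell list gave 1 and 1 of 4 (1 and 1 adjusted over the list alone), the male reproductive tract 0 and 0 of 2 (0 and 0 adjusted over the list alone), both too small for a list test.

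FOXO targets taken from the literature did not move as a list in ageing males. Of 10 tested 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median log2 change of 0.20 (limma camera adjusted p = 0.167). The gene srl rose by 0.77 (SE 0.17, limma adjusted p = 0.00157), bmm by 0.61, Lip4 by 0.55 and NLaz by 0.47, and FoxK fell by 0.38. NLaz lost its call without day 3 replicate 1 (limma adjusted p = 0.0526). The values of Thor (0.14), Ilp6 (0.25), Sesn (0.07), l(2)efl (0.12) and Atg8a (-0.12) did not pass. Of 19 insulin and TOR pathway genes 3 rose, foxo among them, and 3 fell (3 and 3 adjusted over the list alone; median -0.06, limma camera adjusted p = 0.799), including Ilp3 (-1.50) and the kinase gene sgg (-0.30).

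By interval, 531 genes rose and 662 fell from day 3 to day 15, and 1338 rose and 1475 fell from day 3 to day 30, both limma comparisons sharing the day 3 libraries with day 45. From day 15 to day 30, 82 rose and 89 fell (limma). From day 30 to day 45, 25 rose and 12 fell, with 778 genes at an unadjusted p under 0.05 (limma). At any age 2809 genes differed by limma's moderated F test. The counts of single intervals depended on single libraries: day 3 to day 15 gave 624 genes without day 3 replicate 1, 620 without day 15 replicate 1 and 769 without day 15 replicate 3, against 1193 with all. Day 15 to day 30 gave 100, 13 and 62 without day 15 replicate 1, 2 or 3, 22 and 41 without day 30 replicate 2 or 3 and 293 without day 45 replicate 3. Day 30 to day 45 gave 24 without day 15 replicate 2 and 24 without replicate 3, 21 and 3 without day 30 replicate 2 or 3 and 5 and 99 without day 45 replicate 1 or 3.

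The last comparison asked how the genes that differed in the foxo mutant behaved with age in wild-type males. Genes lower in the mutant tended to be lower in old males, and genes higher in the mutant to be higher. Neither trend passed with an estimated correlation between genes (limma camera p = 0.0564 and, for the higher genes, p = 0.0938). The mutant list and the age test share no library, and differ in sex.

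Of the 624 genes lower in the mutant by the authors' deposited table that could be tested with age, 271 fell and 117 rose from day 3 to day 45 (283 and 125 adjusted over the list alone). Their median log2 change was -0.20, below the range of -0.08 to -0.01 that held 95% of 10000 random lists matched on level. Set against the other genes by limma's camera, the list had p = 1.98e-06, and p = 0.0564 with an estimated correlation. The 200 genes lower in the mutant with the smallest p in the authors' deposited table had a median of -0.08 and lost the call (limma camera, p = 0.101). Of the 562 genes higher in the mutant by the authors' deposited table, 229 rose and 66 fell (249 and 75 adjusted over the list alone), with a median of 0.24 against -0.04 to 0.04 for random lists (camera p = 1.3e-07, p = 0.0938 with an estimated correlation). The medians were -0.12 and 0.11 at day 15 and -0.18 and 0.23 at day 30.

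Across the 8571 genes tested in both, 271 were lower in both where independent lists would share 114 (odds ratio 3.93, 95% interval 3.31 to 4.67, Fisher's exact test, two-sided, p = 5.2e-52), and 229 were higher in both where 96.3 would be shared (odds ratio 3.75, p = 4.35e-43). Genes lower in the mutant and higher with age numbered 117 against 107 (p = 0.27), and the reverse 66 against 103 (p = 1.67e-05), by Fisher's exact test. Of 683 genes called in both, 500 changed in the same direction (73.2%, where independent directions give 49.9%). Genes are not independent, so these p-values describe gene lists. Across the 1186 genes called in the mutant and tested with age, the changes correlated with Pearson's r of 0.19 and Spearman's rho of 0.24, a correlation across genes, which are not independent replicates.

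**Figure D4:**
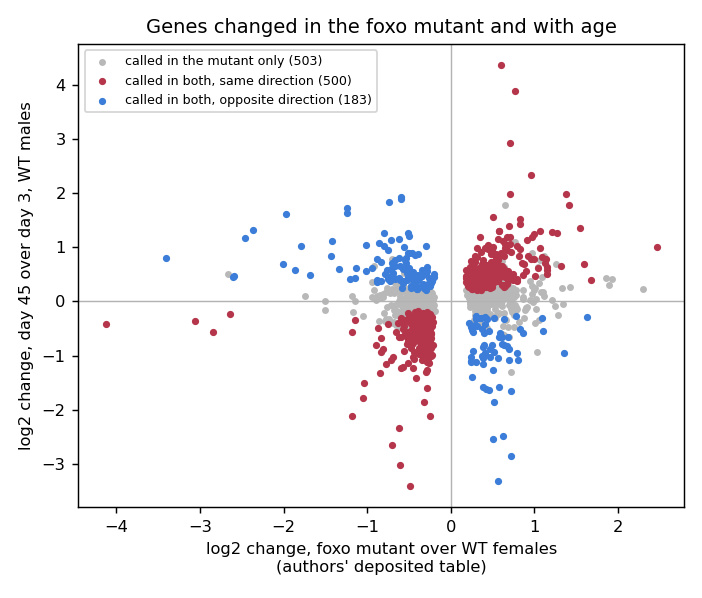
Log2 change in foxo mutant over wild-type females (x axis, from the authors' deposited table) against log2 change from day 3 to day 45 in wild-type males (y axis) for 1186 genes called in the mutant. Red points are 500 genes called in both with the same direction, blue points 183 with opposite directions and grey points those called in the mutant only.

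Genes with large changes of the same direction included Mec2, which was higher in the mutant (log2 change 1.42 in the authors' deposited table) and rose with age from 35.0 ± 5.95 to 122 ± 11.9 normalized counts. CG4927, CG9119 and PGRP-SA were also higher in the authors' deposited table, by log2 changes of 1.55, 1.28 and 1.07. They rose with age by log2 changes of 1.37, 1.27 and 1.31. CG15347 stood at 1.37 in the authors' deposited table and rose with age by a fold of 3.99. Cpr11B and CG4476 were lower in the authors' deposited table (-1.18 and -1.05) and fell with age (-2.12 and -1.79, limma adjusted p = 2.51e-06 and 1.13e-05).

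As a list, genes with at least a 2-fold loss in the mutant had a median of the opposite sign with age. Of the 37 genes at least 2-fold lower in the mutant by the authors' deposited table and tested with age, 20 rose and 9 fell, and their median log2 change with age was 0.45 (limma camera p = 0.015 with the preset correlation). An estimated correlation between genes was not tried for this list. Genes at least 2-fold higher in the mutant by the authors' deposited table had a like median of 0.44, with 20 that rose and 4 that fell, so both lists lay on the higher side. The steepest losses were mixed: sordd2 and asRNA:CR45600 fell with age too, by 0.42 and 0.36 on the log2 scale (limma adjusted p = 0.0105 and 0.0231), while CG3397 rose by 0.80. CG6912 and CG6654, named after their values were seen, stood at -0.56 and -0.23 with age. Ldh, at -1.24 in the authors' deposited table, rose with age from 32.6 ± 5.55 to 104 ± 18.3, and Hpd, at -1.42 in the authors' deposited table, from 537 ± 67.0 to 1168 ± 232 (limma adjusted p = 4.45e-06 and 2.98e-06). Cyp4p2, CG11893 and CG18547 stood at -2.46, -2.36 and -1.80 in the authors' deposited table and rose with age by 1.16, 1.31 and 1.03. MFS3 and Cyp4e3, at -1.98 and -1.24 in the authors' deposited table, stood at 1.61 and 1.73 with age. These calls were lost without day 3 replicate 1 (limma adjusted p = 0.0725 and 0.0532), and that of MFS3 also without day 45 replicate 1 or 2 (limma adjusted p = 0.0574 and 0.0573) and that of Cyp4e3 with DESeq2 on recovered reads (adjusted p = 0.143).

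**Figure D5:**
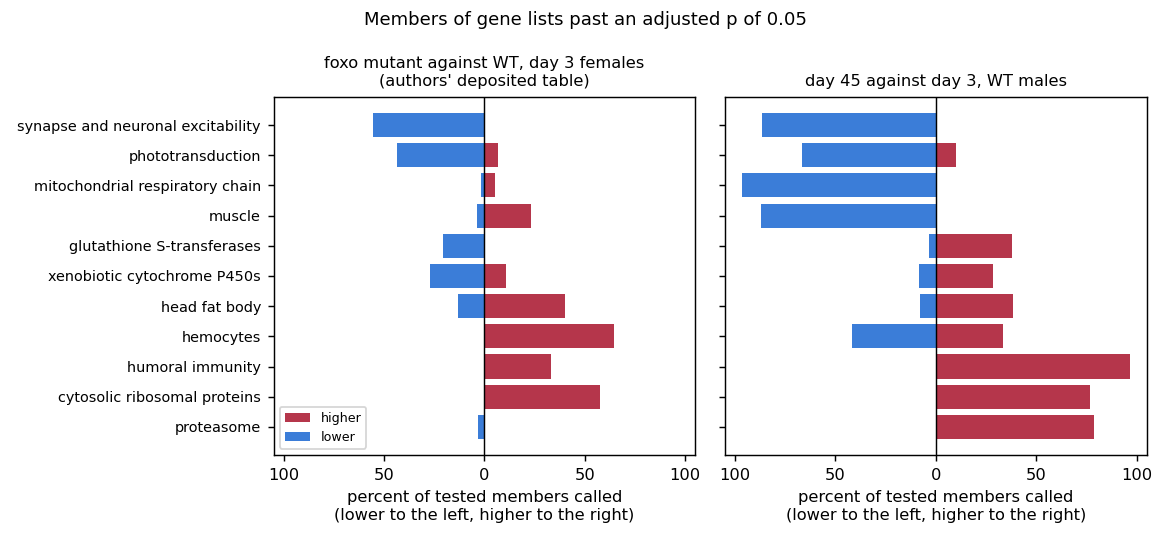
Percent of tested members of 11 gene lists (y axis) that were lower (blue, to the left) or higher (red, to the right) at an adjusted p under 0.05 (x axis), in foxo mutant against wild-type females from the authors' deposited table (left) and in day 45 against day 3 males (right). Synapse genes lie on the lower side in both panels (25 of 45 and 38 of 44) and ribosomal protein genes on the higher side (47 of 82 and 59 of 77). Other lists differ between the panels. Glutathione S-transferases gave 0 higher and 6 lower of 29 in the mutant but 11 higher and 1 lower of 29 with age. Muscle gave 6 higher and 1 lower of 26 in the mutant but 0 higher and 20 lower of 23 with age.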

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

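The alternatives without the libraries that stood apart, the 0.25, 2 and 5 Mb windows, those for foxo itself except rescaling, those for gene lists except the estimated correlation, rescaling and the block, and those for the overlap by edgeR, block or left-out libraries were chosen after the result was seen. Requiring an absolute log2 change of at least 1 left 142 genes from day 3 to day 15, 284 to day 30 and 425 to day 45, 18 from day 15 to day 30, 15 from day 30 to day 45, 445 at any age and 96 in the mutant by the authors' deposited table. Leaving out 1 library at a time gave 620 to 1430 genes from day 3 to day 15, 13 to 293 from day 15 to day 30 and 3 to 99 from day 30 to day 45. From day 30 to day 45, 24 genes were called at a mean of at least 50, 63 by DESeq2 and 56 by edgeR, against 37. From day 3 to day 45, DESeq2 called 2419 and edgeR 3138, and 2298 genes were called by limma without day 3 replicate 1 and day 45 replicate 3, against 3184.

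With an estimated correlation, genes lower in the mutant kept their median of -0.20 at a camera p = 0.0564 (limma) and those higher their 0.243 at p = 0.0938, neither under 0.05, and 0 of the gene lists were called with age, against 15. The list of genes at least 2-fold lower in the mutant had a median of 0.446 with age, and that of genes at least 2-fold higher one of 0.439. The 200 lower genes with the strongest evidence had one of -0.08 and lost the call, so size and direction depend on how the list is drawn. Without both libraries that stood apart the medians were -0.135 and 0.172 and 13 lists were called. Of genes called at least 2-fold in both, 57.9% of 19 changed in the same direction, against 73.2%. The agreement in direction no longer passed there (Fisher's exact test, two-sided, p = 0.228, against 5.28e-36). Within 2 Mb of foxo 19% of genes were called in the authors' deposited table and within 5 Mb 16%, against 17.4% within 1 Mb. The wider windows passed Fisher's exact test (p = 0.000812 and 0.00316), the 1 Mb and 0.25 Mb windows did not (p = 0.102, and 14.3% with p = 0.815).

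Over 29 lists at day 45, 559 alternative results were the same and 19 weaker, and over 140 named genes 2716 were the same, 54 weaker and 2 stronger. A result also counted as the same where neither p passed, whatever its sign, and only 15 lists were called in the main fit. Leaving out a day 15 or day 30 library cannot move a change from day 3 to day 45. Part of the agreement was thus fixed in advance. Of 133 named genes called, 15 lost the call without 1 library and 13 in another fit.

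With the replicate block, 1145, 2760 and 3118 genes were called from day 3 to days 15, 30 and 45, 140 from day 15 to day 30, 43 from day 30 to day 45 and 2748 at any age. The number marks no shared batch in the labels. After each gene's mean at each age was removed, what remained correlated between same-numbered libraries at -0.255 to 0.154, over 0.1 in 2 of 18 pairs. By this measure 3 of 12 libraries correlated best with their own number. The block changed no other call. No paired analysis was possible because the mutant comparison has no value per library. For the same reason rescaling, pseudocounts, left-out replicates, DESeq2, edgeR and camera with an estimated correlation were not run for the mutant.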

Other observations

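The tests of neuron share, of strain differences around foxo, of X-linked genes and of other splits of the libraries were chosen only after the result was seen, apart from the splits for gene lists and for the overlap.

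Blood cell genes that did not move as a list with age held opposite changes. The phagocytic receptor genes NimC1 and Sr-CI rose from day 3 to day 45 by log2 changes of 0.70 and 0.62, while the collagen gene Col4a1 fell by 0.66 and the prophenoloxidase gene PPO2 by 0.58 (limma calls). Genes of chemosensation also differed one by one. In the authors' deposited table Obp99c was lower in the mutant (log2 change -1.18, adjusted p = 1.18e-30) and Obp99b lower (-0.64), and Obp57a (1.06) and Obp19c (0.97) were higher. With age Obp49a (1.06) and Obp56h (0.91) rose and Obp83a (-0.79) fell.

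Clock genes differed in the mutant without a shift of the list. In the authors' deposited table the transcriptional repressor gene cwo (0.56) and vri (0.35) were higher and per (-0.38) and the neuropeptide gene Pdf (-0.43) lower. The antioxidant list held a fall of the mitochondrial Sod2 with age (-0.45) beside a rise of Prx2 (0.31). The roX RNAs fell with age, while X-linked genes lay only -0.039 from autosomal genes in the median log2 change at day 45 (95% interval -0.063 to -0.02, 1443 X-linked genes).

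Genes lower in the foxo mutant had a median log2 change of -0.20 in old males (271 of 624 fell, 117 rose) and genes higher in it one of 0.243 (229 of 562 rose, 66 fell), with camera p = 0.0564 and p = 0.0938 (limma) at an estimated correlation. Exon length correlated across genes with the change at day 45 and in the mutant (Spearman -0.179 and -0.258), but after each library's trend with length was removed the medians were -0.115 (random lists -0.035 to 0.029) and 0.213 (-0.026 to 0.048), so length alone does not account for either, though it took part of the first. Without any member of the fixed lists the medians were -0.201 over 531 genes and 0.225 over 462, so those members are not the whole source. Most genes lay outside the lists, and genes of the same processes that the lists leave out were kept. Those processes as a source were therefore not tested. A lower share of neurons alone would raise markers of all other cell types, whereas muscle lay -0.973 below head fat body. Muscle genes fell themselves (median -0.808), which a lower neuron share could accompany, so this difference does not decide on neuron share. The share of neurons thus stays open. Sex, the genetic background of the mutant and changes within cell types stay open and untested, and a shared response to lost FOXO activity is a hypothesis only, since FOXO activity was not measured and foxo mRNA rose.

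Genes at least 2-fold lower in the mutant had the opposite sign, with a median of 0.446 at day 45 over 37 genes (SE 0.176, random lists -0.129 to 0.174). Without genes within 5 Mb of foxo the median was 0.501 (28 genes), which argues against genes within that window as the source. Genes farther along the same chromosome arm were kept, so linkage over a longer stretch was not tested. After the length trend was removed it was 0.405 (SE 0.189), above the random range of -0.127 to 0.158. Differences between the stocks elsewhere in the genome may still contribute at this 0.446 and were not tested.

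In a permutation test, calls of at least 2-fold in the mutant lay next to each other more often than shuffled calls, with 7 adjacent pairs of genes against 0.853 (p = 1e-04, the smallest that 10000 shuffles can give). Chosen after their values were seen, CG18547, CG12224 and CG3397 (2.07 Mb from foxo) and CG6912, asRNA:CR45600 and CG3987 (1.05 Mb), where copies or overlapping genes may share reads, made up 4 pairs, and Srg1 with Elal (10.8 Mb), CG11841 with CG11842 (15 Mb) and CG13965 with CG16772 (arm 2L) the other 3. As many genes of largest change with age held 13 adjacent pairs against 0.952, so neighbours changed together without a mutation too. Genes of largest change with age include neighbouring members of gene families, such as DptA and DptB. Their pairs therefore cannot tell whether shared change of neighbours accounts for the pairs in the mutant. Strain differences around foxo stay open too, since arm 3R held 1.35% of genes called with at least 2-fold against 0.807% elsewhere (p = 0.0209) and 5 Mb around foxo 1.46% against 0.892% (p = 0.102; Fisher's exact test, two-sided). Calls not within 5 Mb held 3 pairs against 0.689 shuffled (p = 0.031), but calls off arm 3R held 1 pair against 0.47 (permutation test, p = 0.377). This test counts only adjacent genes and misses looser groups. Picked after their values were seen, CG5966, MCTS1, CG4660 and Ubi-p5E, all at least 2-fold lower, lay between 5988791 and 6279647 on X. Whether such a group exceeds random placement was not tested, so the pairs do not decide where stock differences lie.

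With 3 libraries per age there are 10 splits, too few for a share under 0.05. In each of these results 1 of the 10 splits, the real one, was as large. The real counts and the highest of the other splits were 1193 and 0 from day 3 to day 15, 2813 and 0 to day 30, 3184 and 0 to day 45, 171 and 1 from day 15 to day 30, and 37 and 4 from day 30 to day 45. They were -0.20 and 0.117 for the median of genes lower in the mutant, 0.243 and 0.151 for genes higher in it, 15 and 13 for gene lists called with age, and 500 and 0 for genes called in both with the same direction. The last 0 was fixed in advance, since the other splits called 0 genes from day 3 to day 45, so it is no evidence on the overlap. For a difference at any age, 1 of 100 splits was as large, the real one with 2809 genes against at most 1527 in the others. This share is under 0.05 and the smallest that 100 splits can give. It treats the libraries as exchangeable, and the labels do not say whether replicates were separate collections.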
